A study of Caenorhabditis elegans with 2 samples.

How the data were processed

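The data were transcription factor ChIP-seq peak lists from whole *Caenorhabditis elegans* young adults, collected 63 h after growth was started from synchronised, starved first-stage larvae. The worms carried a tag with green fluorescent protein (GFP) inserted by CRISPR into *egl-18*, so that an antibody against GFP precipitates the EGL-18 fusion protein with the DNA it is bound to. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp. There was 1 group with 2 samples, which the labels number as biological replicates 1 and 2. The labels name possible controls, and no control library was analysed here.

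The deposited material consisted of 8 peak lists on genome assembly ce11, per the file headers and accompanying descriptions. Each replicate had 2 lists and the series had 4. In each case, ranked lists hold every peak compared by the irreproducible discovery rate (IDR), which asks whether a peak ranks alike in 2 inputs, and thresholded lists hold the peaks that passed. Each replicate's own lists were called from that replicate alone, and the series-level lists were derived from the alignments of both replicates, per the deposited descriptions. The aligner, the peak caller, their versions and the settings are not given in the sources used here. The signal column of the deposited lists is the height of a peak as the authors' peak caller gave it, on a scale that is not stated. It was used only to rank and describe peaks within a list. The score column deposited by the authors is the smaller of 1000 and -125 times the base-2 logarithm of the global IDR. At least 99.99% of the peaks of each ranked list lay within 1 of the value computed from its IDR column. The −log10 columns deposited by the authors hold the q-value of a peak and its local and global IDR. A peak list has no read counts, so the depth of the libraries is unknown. Intervals on shares are exact Clopper-Pearson 95% intervals and cover the number of regions only.

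The main set was the series-level thresholded list of 699 peaks, of which overlapping peaks were merged to 684 regions, each with the summit and signal of its strongest peak. All 699 peaks were found in 1 of the series' ranked lists. That ranked list holds 800 peaks with a score of 830 or more, and 101 of them are not in the main set. The thresholded lists were derived from 1 more file than the ranked lists, and that file was not used here. In the other series-level ranked list, 99.4% and 99.0% of the input heights at scores of 830 or more occur in the lists of replicate 1 and replicate 2. Over all peaks of that list, these shares were 52.1% and 49.2%. The 2 columns of input heights of that list were used for the correlation between replicates. The 2 such columns of the first ranked list were not tied to a replicate and were not used.

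Chromosome lengths and sequence came from the WBcel235 assembly, which is the same as ce11, and no peak ended beyond a chromosome end. Genes came from Ensembl release 115. A summit was called promoter when it lay from 1000 bp upstream to 200 bp downstream of a start of a protein-coding transcript. Other summits were assigned, in order, to exons, introns, the surroundings of non-coding RNA genes, or intergenic sequence. A target gene was a gene with a summit in its promoter window, so that a region could have 2 or more targets, as 77 of the 302 promoter regions did. The background of gene list tests was 19978 genes, the protein-coding genes and 5 microRNA genes of the lists.

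Overlap between replicates (at least 1 bp) and location shares were tested against 10000 placements in which regions were shifted around their chromosomes by random distances, called permutation tests here. The smallest p these placements can give is 0.0001. The share on X was tested with a two-sided exact binomial test against its share of the sequence. GATA sites (WGATAR, where W is A or T and R is A or G) were searched on both strands within 75 bp of the summit. Their share was compared by two-sided Fisher's exact test with 2 windows of 151 bp per region, 600 bp to either side, leaving out those that met another region. The 2080 6-mers, each taken with its reverse complement, were tested in the same windows. Fisher's exact test was also used for 15 gene lists and for the 94 gene name classes with at least 20 genes. P-values of a family were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

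The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named genes were the targets of the 20 strongest regions, or their nearest gene, the *egl-18* and *elt-6* loci with 5000 bp on either side, up to 4 targets per gene list by signal (all targets of the GATA, seam cell and heterochronic lists), the 10 strongest targets in both replicates' lists, and the 10 6-mers with the smallest adjusted p. Other named items were chosen after their values were seen. The share of regions at RNA genes (tRNA, snoRNA and snRNA genes within 150 bp of the summit) was added after seeing the data, as were comparisons with genome windows matched on GC content (10 per region), a score of 1000, repeats without the regions at RNA genes, the promoter window of 500 to 100 bp for gene classes, and the tests of an X chromosome motif, of tRNA genes on X and of GATA sites down the ranked list. The ribosomal protein list was written as name prefixes. These were at first read as names ending in a digit, which gave 13 targets of 76 genes. After the results had been seen, the reading was widened to every name with the prefix, which adds *rpl-7A* and gives 14 of 78. The call was the same with both. The planned stricter IDR of 0.01 removed no peak, since every thresholded list has a lowest score of 830 or above.

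The tests were tried on simulated data. For 6-mers, both sides were flank windows of the real regions, so their base composition was alike. With TGATAA planted in 10% of the windows taken as summits, it was recovered among 2080 6-mers. With 0% planted no 6-mer was called, and with 40% planted 6 others were. Real summits and flanks differ in GC content, so false calls between them were not measured. With no shift towards promoters, 11 of 200 simulated sets passed the placement test, and with 10% of regions moved into promoters 200 of 200 passed. With 5 regions added at starts of ribosomal protein genes, the list was recovered in 100 of 100 runs. Other lists gave 6 calls over those runs. The added regions lay inside promoter windows by design.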

Results

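EGL-18 is a GATA-type transcription factor known for its part in the seam cells of the epidermis and in vulval development. The peak lists give the places in the young adult genome called as peaks after precipitation of the GFP-tagged protein, from 2 biological replicates and without a control list here. The main set held 684 regions covering 187049 bp, with a median peak width of 276 bp and a median peak signal of 81.6 (range 2.64 to 544). Signal is the authors' peak height, and the depth of the libraries is unknown. The thresholded list of replicate 1 held 194 regions and that of replicate 2 held 228.

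The strongest regions lay at the same places in both replicates. Of the 20 strongest regions of the main set, 19 were in both replicates' lists, headed by the region upstream of *rpl-3*, which encodes a protein of the large ribosomal subunit. Signal in the main set derives from both replicates together, so ranking by it favours regions that are high in both. Of the 194 regions of replicate 1, 127 (65.5%, 95% interval 58.3 to 72.1) overlapped a region of replicate 2, which was 55.7% of the regions of replicate 2 (49.0 to 62.3). Random placement gave a mean of 0.231 shared regions (one-sided permutation test, p = 0.0001, the smallest that 10000 placements can give). Of the 684 regions, 18.3% were in both replicates' lists, 8.48% in that of replicate 1 only, 12.7% in that of replicate 2 only and 60.5% in neither. The inputs compared by IDR for the main set were not tied to the replicates, so a place in that set is not by itself taken as agreement between them. The median signals of these classes of regions, in the order given, were 160.0, 96.7, 96.0 and 75.3, which the combined signal also favours. The other series-level ranked list, whose inputs were matched to the replicates, shares 694 peaks with the main set. Across these peaks, heights in the 2 replicates correlated with a Spearman's rho of 0.34 and a Pearson's r of 0.49 on log2 heights. The 95% interval of rho was 0.26 to 0.41, from a bootstrap that resamples peaks. Peaks are not independent replicates, so the interval covers peaks only and no p is given for the correlation. Across all 109080 peaks of that ranked list, rho was 0.24, but only 52.1% and 49.2% of their heights occur in the lists of replicates 1 and 2.

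Of the 20 strongest regions, 4 had ribosomal protein genes as targets. The first region, at III:3867468-3867665 (ce11), lay 288 bp upstream of *rpl-3* with a signal of 544, and had heights of 219 in replicate 1 and 324 in replicate 2. The regions ranked 9, 10 and 11 lay upstream of *rpl-35* (III:7854619-7854756, signal 286), *rpl-15* (IV:654877-654996, signal 282, shared with *K11H12.8*) and *rpl-20* (IV:4750008-4750146, signal 279, shared with *Y17G9B.5*). The region ranked 7 (II:11759411-11759513, signal 292) lay between the divergent genes *F44E5.4* and *F44E5.5*, which encode Hsp70 family chaperones. That ranked 6 (II:10563495-10563642, signal 317) lay upstream of *cdc-48.1*, an ATPase that unfolds ubiquitinated proteins. Other promoter regions among the 20 strongest were those of *tasp-1* with *K01G5.10* (signal 416), *rpa-2* (324), *nspc-17* (254) and *mog-4* (253).

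The other 10 of these 20 regions were not in promoters, and 5 of them were intergenic, 3 intronic and 2 near non-coding RNA genes. The second strongest (IV:4725503-4725710, signal 429) lay near *K08F11.1*, as did the region ranked 13 (signal 274). Intronic regions in *frm-7* (V:12303560-12303724, signal 338) and *pxn-1* (V:8500512-8500602, signal 258) lay at snoRNA genes, *C51F7.3* and *C51F7.4* in the first and *ZK994.7* in the second. The region ranked 19 (signal 254) was in an intron of *Y41G9A.17*. The genes nearest to the others were *F55C5.17* for the *frm-7* region, *F20B6.9* (1801 bp from its start), *K02D3.1* (6045 bp), *W02H3.3* (3983 bp), *K07D4.2* (2573 bp) and *srv-14* (1840 bp). The last of these, at IV:15895935-15896210, was in the list of replicate 1 only.

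At its own locus, EGL-18 had 1 peak, in an intron of *egl-18* (IV:1908582-1908857, signal 81.1, score 1000). It ranked 356 of 699 peaks and was in neither replicate's list, with heights of 46.1 and 36.7 in the ranked lists of replicates 1 and 2. No peak of the main set lay within 5000 bp of *elt-6*, the neighbouring GATA factor gene.

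Promoters were over-represented among the regions. Of the 684 summits, 302 (44.2%, 95% interval 40.4 to 48.0) lay in a promoter, against a mean of 25.9% in random placements (two-sided permutation test, p = 0.0001). The share was 42.3% in replicate 1 and 49.1% in replicate 2. Exons held 11.3% of summits against 21.6% at random and introns 15.8% against 27.2% (permutation test, adjusted p = 0.000125 for both). Intergenic sequence held 16.08% against 18.5% (permutation test, adjusted p = 0.122), which did not pass the test. Exons held 3.61% and 4.39% of the summits in the lists of replicates 1 and 2, a difference from the main set that was not tested.

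Genes for tRNAs, snoRNAs and snRNAs also gathered regions. A summit lay within 150 bp of such a gene in 17.4% of the 684 regions (14.6 to 20.5), against 0.435% in random placements (two-sided permutation test, p = 0.0001). There were 68 regions at tRNA genes (1.64 in random placements), 35 at snoRNA genes (1.00) and 16 at snRNA genes (0.337), each with an adjusted p of 0.0002 in the permutation test. Among them were 6 regions at genes of spliced leader RNAs, which are joined to messenger RNAs in trans, chosen after their values were seen. The strongest were at *sls-2.1* (II:5844756-5844842, signal 221) and *sls-2.4* (I:4172127-4172402, signal 213). Of the 6, 3 were in both replicates' lists, 1 (at *sls-2.8*) in that of replicate 1 only and 2 in neither. The share was 25.3% in replicate 1 and 19.3% in replicate 2. Genes annotated as ncRNA, a class that can share regions with the others, had 133 regions against 20.98 at random (permutation test, adjusted p = 0.0002). By the same permutation test, 2 regions lay at microRNA genes (adjusted p = 0.194), 0 at the 20 annotated rRNA genes (adjusted p = 1), and 3 at piRNA genes against 17.4 at random (adjusted p = 0.00333). Pseudogenes held 10 regions against 24.6 at random (permutation test, adjusted p = 0.00914).

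**Figure D1:**
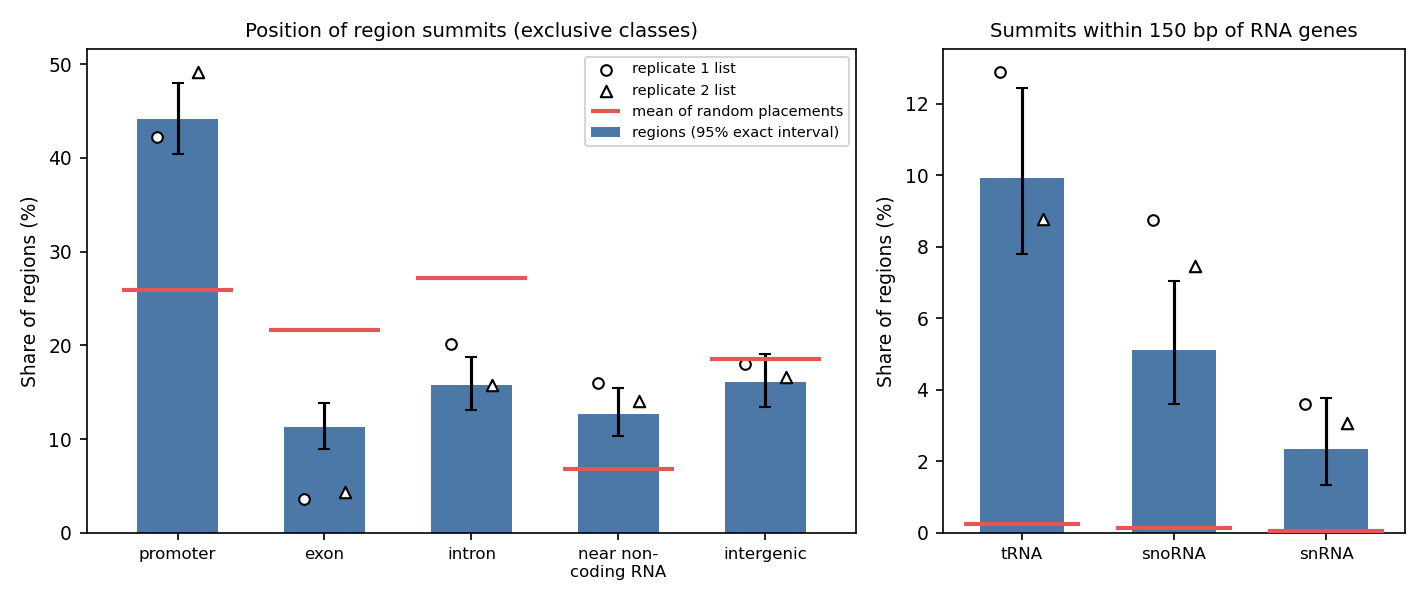
Share of regions (percent) by the position of the summit (left, exclusive classes) and within 150 bp of tRNA, snoRNA or snRNA genes (right). Bars show the 684 regions with exact 95% intervals, circles and triangles the lists of replicates 1 and 2, and red lines the mean of random placements; promoters held 44.2% of summits against 25.9% at random.

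Among the 15 gene lists, the ribosomal proteins alone passed the test. Of their 78 genes, 14 were targets against 1.47 by chance (odds ratio 11.8, Fisher's exact test, adjusted p = 2.84e-09). Besides the 4 above, these were *rpl-7A* (signal 247), *rpl-11.2*, *rpl-16*, *rpl-27*, *rps-1*, *rps-8*, *rps-12*, *rps-19*, *rps-23* and *rps-24*, several of them named after their values were seen. Their regions had a median signal of 153, and 8 of the 14 were in both replicates' lists. The name classes *rpl* (8 of 47, adjusted p = 0.000228) and *rps* (6 of 31, adjusted p = 0.000992) passed separately among 94 classes in the exact test. The class *hsp* also passed (4 of 22, exact test, adjusted p = 0.0216), with *hsp-90* (signal 196), the mitochondrial chaperonin *hsp-60* (162), the Hsp70 gene *hsp-1* (148) and *hsp-3* (121). It did not pass with the nearest gene start (2 of 22, exact test, adjusted p = 0.823) or with a promoter window of 500 bp upstream to 100 bp downstream (3 of 22, adjusted p = 0.0838), an alternative added for classes after seeing the data.

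The list of heat shock and stress genes had 3 targets of 22 (*hsp-90*, *hsp-60* and *hsp-1*) against 0.414 by chance. All 3 were in both replicates' lists. Its adjusted p of 0.0586 in the exact test did not pass, whereas it passed with the list of either replicate alone (0.00169 for replicate 1 and 0.0044 for replicate 2). With the nearest gene start it had 1 target (exact test, adjusted p = 0.666), and with the window of 500 bp upstream to 100 bp downstream 2 (adjusted p = 0.239).

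The lists nearest to the known roles of EGL-18 were too short for a lack of targets to be told from chance, which gave from 0.245 to 0.565 targets per list. By Fisher's exact test there were targets among 0 of 13 genes for GATA factors and cofactors (adjusted p = 1), 0 of 30 seam cell and Wnt asymmetry regulators (adjusted p = 1) and 0 of 25 genes of epidermal and molting structure (adjusted p = 1). The heterochronic list, of genes that time larval development, had *lin-46* (1 of 16, signal 84.7, exact test, adjusted p = 0.833). The vulval and egg-laying list had 2 of 20 (exact test, adjusted p = 0.269), *egl-17*, a fibroblast growth factor gene, and the homeobox gene *unc-62*. The summit at *egl-17* lay at a tRNA gene. Of the collagens 1 of 174 was a target (*col-142*, exact test, adjusted p = 0.833), and of the nuclear hormone receptors 4 of 269 (*nhr-255*, *nhr-47*, *nhr-286* and *nhr-34*, adjusted p = 1). The muscle list had the actin gene *act-4* (1 of 20, exact test, adjusted p = 0.833) and the neuron list the glutamate transporter gene *eat-4* (1 of 24, adjusted p = 0.833). The intestine list (22 genes), the germline and oocyte list (22), the *hlh* genes (25) and the *ceh* homeobox genes (63) had 0 targets (exact test, adjusted p = 1 for each).

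GATA sites were less frequent at the summits than in the sequence beside them. A WGATAR site lay within 75 bp of 104 of 684 summits (15.2%, 12.6 to 18.1) and in 24.4% of 1332 flanking windows (odds ratio 0.56, 95% interval 0.44 to 0.71, two-sided Fisher's exact test, p = 1.30e-06). The share was 10.3% in replicate 1 and 12.7% in replicate 2, and 1 of the 20 strongest regions had a site. The summits were richer in G and C than the flanks (47.8% against 37.3%). Against genome windows of the same GC content, an alternative added after seeing the data, the odds ratio was 0.78 (0.62 to 0.96, exact test, p = 0.0228). Among the 228 strongest regions 12.7% had a site, and among the 228 weakest 19.7%, a difference that did not pass the exact test (p = 0.0562).

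**Figure D2:**
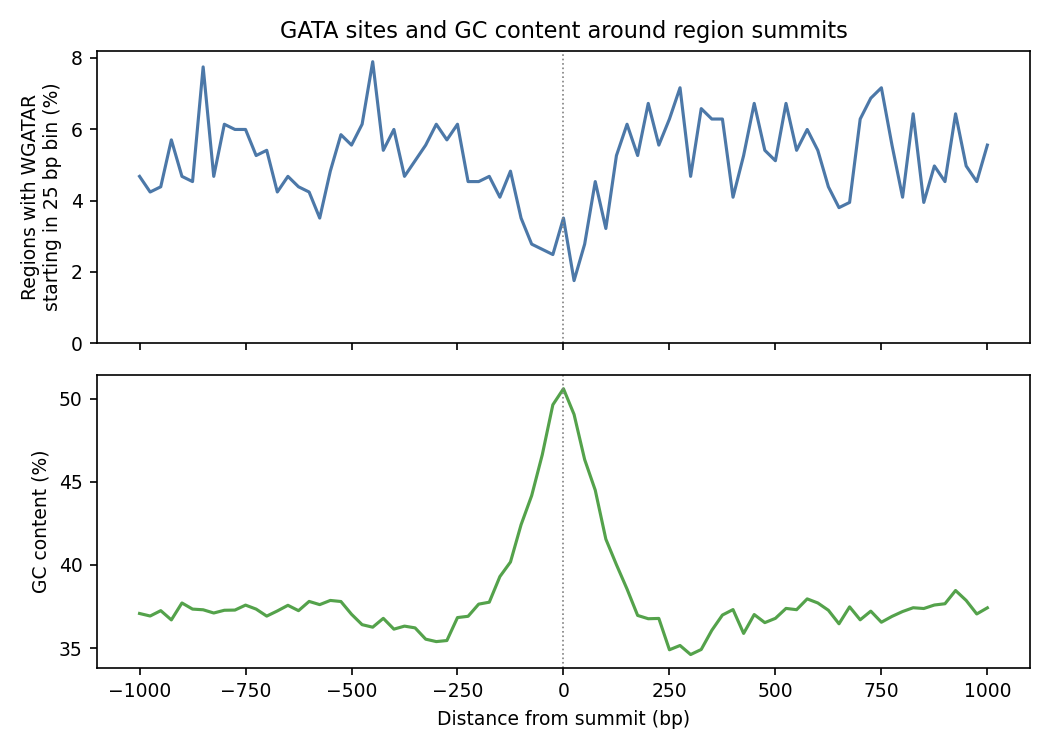
Share of the 684 regions with a WGATAR site starting in each 25 bp bin (percent, upper panel) and mean GC content (percent, lower panel) by distance from the summit in bp. The share of sites falls to 1.75% in the bin at 25 bp, and GC content rises to 50.6% at the summit.

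Short sequences with CG steps were the most enriched at summits. Of the 6-mers tested, 495 were enriched and 336 depleted relative to the flanks. CGCGCA was present in 14.9% of summit windows and 1.95% of flanks (odds ratio 8.80, exact test, adjusted p = 3.67e-25), ACGCAG in 15.9% and 2.63% (7.02, adjusted p = 1.06e-23), AGCGCG in 12.4% and 1.65% (8.45, adjusted p = 9.93e-21), and ACGCGC in 13.3% and 2.18% (6.89, adjusted p = 8.86e-20). The other 6 of the 10 with the smallest adjusted p were depleted A- and T-rich sequences: AAAAAT, TAAAAA, TGAAAA, TCAAAA, TTAAAA and AAAATT. Against GC-matched windows 0 of these 6 were depleted (odds ratios from 0.774 to 1.31), and AAAATT was enriched (1.31, exact test, adjusted p = 0.0201). Against GC-matched windows 216 were enriched and 227 depleted, and 179 were enriched in both comparisons, the 4 named ones with odds ratios from 3.02 to 4.03. Of the 4 6-mers that make up WGATAR, 0 were enriched relative to the flanks. AGATAA (odds ratio 0.388) and TGATAA (0.431) were depleted there, but not against GC-matched windows (0.666, exact test, adjusted p = 0.184, and 0.751, adjusted p = 0.267). Relative to the flanks, CTATCA had an odds ratio of 0.578 (exact test, adjusted p = 0.0795) and AGATAG had an odds ratio of 1.64 with an unadjusted p of 0.0599.

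The X chromosome held more regions than its share of sequence. It had 155 of 684 regions (22.7%, 19.6 to 25.99) against 17.7% of the sequence (two-sided exact binomial test, p = 0.000918, adjusted p = 0.00551 over 6 chromosomes). The shares were 26.8% in replicate 1 and 25.9% in replicate 2. Chromosome V had fewer regions than its share (16.7% against 20.9%, exact test, adjusted p = 0.0189). Without the regions at tRNA, snoRNA and snRNA genes, X held 109 of 565 regions (19.3%, 16.12 to 22.8, exact test, p = 0.321), which did not pass the test.

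**Figure D3:**
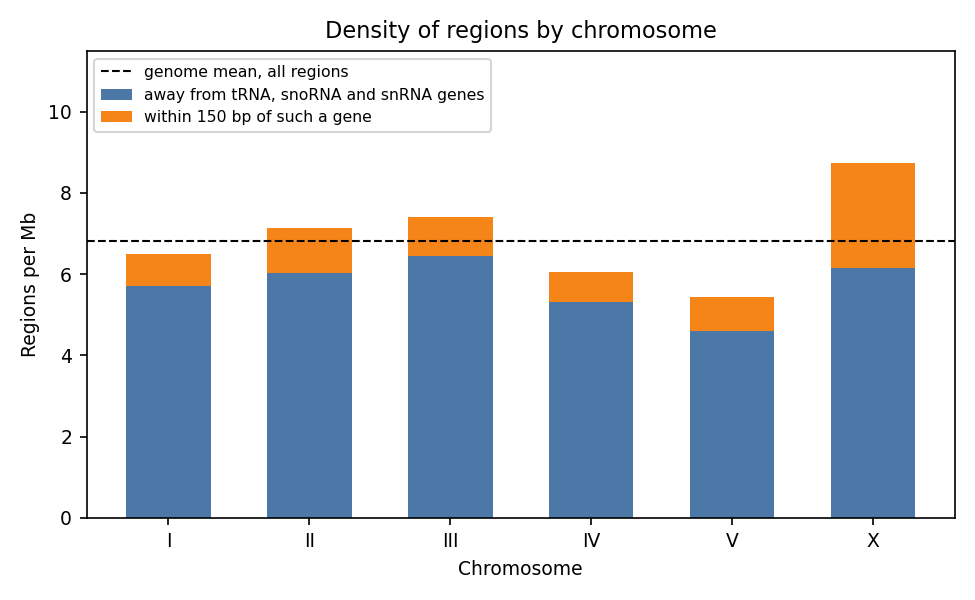
Regions per Mb on each chromosome, split into those within 150 bp of a tRNA, snoRNA or snRNA gene (orange) and the others (blue), with the mean of all regions over the genome as a dashed line. X has 8.75 regions per Mb, of which many lie at such genes, and V has 5.45.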

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

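Of the 800 peaks of the ranked series-level list with a score of 830 or more, the 12.6% that are not in the main set were looked at because they lie outside the comparisons above and include the strongest peaks of all. Their highest signal was 3122.5, at X:15810945-15811178, against 544.2 for the strongest peak of the main set, and their median was 114 against 81.6. They made up 14 of the 20 strongest peaks with that score. Of these peaks, 21 were on X, 0 lay at tRNA, snoRNA or snRNA genes (upper 95% limit 3.59%), and 7 (6.93%) had a WGATAR site within 75 bp of the summit. The rule by which they were left out is not given in the sources used here. Whether they were removed as artefacts is therefore open, and their signal is not read as binding. The replicates' own thresholded lists also lacked peaks with a score of 830 or more. These were 81 of 280 (28.9%) for replicate 1 and 47 of 279 (16.8%) for replicate 2, and the overlap of replicates was taken without them.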

How the results depend on the processing

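A score of 1000, GC-matched windows, repeats without regions at RNA genes and the narrower window for gene classes were chosen after seeing the data. The narrower reading of name prefixes came first, and the wider one of the main result was chosen after seeing the data. An IDR of 0.01 removed nothing, says nothing of stability and is not counted here. Unmerged peaks are counted, although they left the number of target genes unchanged and so say little on gene lists and classes. Of 72 other alternatives of the results fixed for testing or added later, 56 kept direction and side of the threshold, stayed within 1.5 times the count or, for the correlation, within its bootstrap interval. Promoter share (31.4% to 58.9%, 9 of 9) and overlap of replicates (56.2% to 64.9%, 3 of 3) kept theirs in all that were run. So did the share at RNA genes (17.2% to 25.3%, 6 of 6) and fewer GATA sites (odds ratio 0.336 to 0.776, 13 of 13). As backgrounds for GATA sites, only dinucleotide shuffles (0.762, exact test, p = 0.0135) and GC-matched windows (0.776, p = 0.0228) had the GC content of the summits. The other GATA alternatives used backgrounds poorer in G and C, such as random promoters (34.9% against 48.0%, odds ratio 0.336). These others thus do not separate the scarcity of sites from base composition. The reciprocal overlap used 1000 placements. Single-replicate lists gave 194 and 228 regions and 201 and 225 enriched 6-mers, and a score of 1000 gave 371 regions, all from fewer peaks. GC-matched windows gave 216 enriched 6-mers. The correlation between inputs was 0.244 over all ranked peaks. X held 19.3% without regions at RNA genes (exact test, p = 0.321). Enriched gene lists numbered 2 in place of 1 with the conservative list, each replicate left out, a score of 1000, without RNA genes and with shifted regions, because heat shock and stress passed there (adjusted p 0.00169 to 0.0426). Over its other alternatives that list's adjusted p reached 0.666, with the nearest gene start. Enriched classes numbered 6 with the nearest start (1 more, *srh*, was depleted), 9 with shifted regions and 2 with the narrower promoter window, in place of 3. The *hsp* class did not pass with the nearest start or the narrower window, and its adjusted p ranged from 0.000267 to 0.823. The cause was not tested where none is given.

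Of 150 alternatives of single lists, 19 crossed the number of targets given by chance, in 10 lists, and 0 of the 19 passed the threshold. The 150 include the narrower reading of prefixes for lists without a prefix, which it cannot change. They also include unmerged peaks, which gave each list the same number of targets as the main set. With the nearest start, GATA factors and seam cell regulators had 1 target each, *hlh* genes and intestine 2, collagens 7 and nuclear hormone receptors 10. The last had 4 against 2.40 with shifted regions, and intestine had 1 in the conservative list. Heterochronic, muscle, neuron and vulval lists fell to 0 in smaller sets of regions or a narrower window. The unknown depth and the lack of a control list limit what weak regions can show.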

Other observations

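The motif of the X chromosome, the tests of X without regions at RNA genes, with or without the motif, the test of tRNA genes on X, the shares down the ranked list and the repeat-free share were chosen after results had been seen, as was the share at RNA genes itself. On X, 16 of 155 regions (10.3%, 95% interval 6.02 to 16.22) held a match with at most 2 mismatches to TCGCGCAGGGAG, the sequence known as the recruitment motif of the dosage compensation complex, which lowers expression from both X chromosomes in hermaphrodites. On the autosomes 4 of 529 regions did (0.756%), and in the flanks 3 of 1332 windows (odds ratio of X against autosomes 15.1, two-sided Fisher's exact test, p = 5.24e-08). The 16 regions were strong, with a median signal of 175 against 80.99 for the others on X. They included 4 of the 5 regions on X among the 20 strongest, at X:4209223-4209352, X:11094161-11094278, X:14525847-14525983 and X:2996997-2997126, and 1 near *xol-1*, the gene that sets sex by X dose (X:8036385-8036453, signal 191). Of the 16, 11 were in both replicates' lists and 13 lay outside promoters.

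Genes for tRNAs on X had regions more often than those elsewhere, by a test that counts genes as independent although the 75 genes with a summit share 68 regions. On X, 51 of 276 tRNA genes (18.5%) lay within 150 bp of a summit, and on the autosomes 24 of 336 (7.14%, odds ratio 2.95, two-sided Fisher's exact test, p = 3.35e-05). Of the 68 regions at tRNA genes 46 (67.6%) were on X, which holds 45.1% of tRNA genes. Of 35 regions at snoRNA genes and 16 at snRNA genes 0 were on X, which holds 9.54% and 2.33% of these genes, and no test was run on them. Further down the ranked list, the share of peaks with a WGATAR site was 12% in the first 500 by signal and 27.4% from rank 50001 to 100000, and GC content was 46.7% and 37.7%.

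The scarcity of GATA sites at summits was set against 2 technical explanations. GC content as the whole cause is argued against by the odds ratio of 0.776 against genome windows of the same GC content (exact test, p = 0.0228), though the move from 0.556 shows that part of the difference goes with composition. Dilution by weak regions would give a higher share in the strongest regions, and the split on signal argues against that. In the 228 strongest regions the share differed by -7.02 percentage points from that of the 228 weakest (-13.8 to -0.280). This interval uses a normal approximation, and the difference did not pass the exact test (p = 0.0562). The share was thus not seen to be higher in strong regions, and a lower share there is not established. Without a control list a high signal does not by itself mark binding of EGL-18, so bound sites could be diluted among strong regions too. Binding through other proteins or open chromatin stays possible and was not tested. No biological explanation of this scarcity was tested.

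For the regions at tRNA, snoRNA and snRNA genes, the median share of 50-mers repeated elsewhere was 5.88% of a window, against 0% for the other regions, and 43.7% of windows at RNA genes against 81.4% of the others had no repeat. The median does not decide whether shared reads are the cause, since a window also takes in sequence beside the gene. Exact repeats of 50 bp as the whole cause are argued against by the repeat-free windows at RNA genes. These made up 7.60% of all regions, against 0.435% at such genes in random placements. Copies that differ in a few bases, and repeats shorter than 50 bp, are missed by this count, so reads shared between near-identical copies stay possible. GC content is argued against by the 1.07% of GC-matched windows that lie at such genes, against 17.4% of regions. Whether these are sites that any precipitation enriches cannot be told apart from binding of EGL-18, since 0 of the lists here come from worms without the tagged protein. The same holds for promoters of ribosomal protein and *hsp* genes and for the regions on X with the motif, which was not tested.

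Motif sites alone as the whole cause of the excess on X are argued against only weakly. Of the regions without a match of at most 2 mismatches, 20.9% were on X (17.9 to 24.2, against 17.7% of the sequence). The exact binomial p of 0.0324 is unadjusted, and the lower bound lies close to the share of sequence. Regions with weaker matches count as without the motif here, so they could hold up this share. GC content is argued against by the 16.55% of GC-matched windows on X. With both motif sites and regions at RNA genes left out, 17.1% of 545 regions were on X (upper 95% bound 20.5, exact binomial p = 0.779). Without the regions at RNA genes alone, 19.3% were on X (exact binomial p = 0.321), with an interval up to 22.8 that takes in both the share of sequence and the 22.7% of all regions, so that test does not decide. A candidate explanation is that these kinds of site make up the excess, a hypothesis found and tested on the same regions, and whether both are needed stays open.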
